A study of Mus musculus and synthetic construct with 15 samples.

How the data were processed

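The data are counts per region from 15 libraries of a reporter assay in mouse heart: 5 of RNA from atria, 5 of RNA from ventricles and 5 of DNA of the AAV pool. Groups and replicate numbers were taken from the labels. Per the labels' protocols, RNA was extracted with Trizol and column-purified, AAV genomes were released with proteinase K, and both were copied with a primer carrying a molecular identifier (UMI) at the cloning site and amplified with sequencing adapters. The submitters' processing notes name cutadapt 2.5, Bowtie2 2.3.4.3 and the build mm10. The deposited values are whole-number counts per region, not normalized by the authors. Whether they are reads or UMI-collapsed molecules is not given in the sources used here, so counting intervals and zero-count limits (3 counts) cover counting error only. A table of the whole series held the same counts, with 0 differing values, and a column that assigns each region to a group.

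Each of the 3820 regions is 400 bp long. A region was assigned to the protein-coding gene whose body lies nearest to its midpoint within 100 kb in the RefSeq annotation of GRCm38 (the same build as mm10), with ties going to the shorter gene, and 3424 regions had one. The plan named the nearest transcription start site, but the table used here gives no strand, so the gene body was used, and exons and introns were not told apart. Motif tests planned on the regions' sequences were not run because no genome sequence was used here. Class tags were read from the identifiers: a region can carry several tags, and aMTF, vMTF, GeneAVB, p300AVB and ESC-Neg are used as given.

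Replicate pairs were compared by chi-square over regions with at least 10 counts in the pair. No pair agreed within sampling noise: the lowest chi-square per degree of freedom was 1.79 in DNA, 17.7 in atrial RNA and 12.7 in ventricular RNA. If the counts are reads, technical repeats could differ by as much, so this does not show that the libraries are independent, and all 15 were kept as samples as the labels list them.

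Each comparison was tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (robust, TMM factors) on the 5 and 5 libraries compared, over the 2601 regions with a mean of at least 10 counts in DNA. P-values were adjusted by Benjamini-Hochberg over the regions, and calls have an adjusted p under 0.05. Standard errors were computed from the log2 fold change and the F statistic. CPM are after TMM scaling within a comparison unless stated. The log2 fold changes of RNA over DNA are relative to the bulk of the library. Classes and gene lists with at least 5 tested regions were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, and adjusted over 14 classes or 6 lists per comparison. Fry of limma, which tests a set against no change instead of against the other regions, was run beside camera. Its values are given for the lists only. Differences between classes over regions used 100000 permutations of the region labels, two-sided, and 20000 in the alternatives. Per-library class values are means of log2 CPM (prior count 2) minus the mean of the DNA libraries, compared by an exact permutation test that treats the libraries as unpaired. The gene lists, the tests of regions, the class tests by camera and by permutation over regions, the list tests and the rule for named regions were fixed before the data were examined, as were all alternatives except the added ones. The exact permutation test on per-library class values, the choice of tags used as classes and the tests of explanations were not part of that plan.

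The rule for named regions takes, for atrium against ventricle, the 12 largest changes in each direction among regions that passed and whose libraries did not overlap, for each RNA over DNA comparison the 10 highest and 4 lowest by the same rule, and for each gene list up to 4 members with the smallest p that passed between chambers. Regions tagged ESC-Neg were left out of this rule and are described as a class. 1 region that the rule selected is not reported here and was not replaced, and it stays in all counts of regions.

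In simulated counts with the real means and library sizes, 200 regions were changed by known folds. For atrium over DNA 38.8% of 1.5-fold, 86.6% of 2-fold and 95.5% of 4-fold changes were recovered. For ventricle over DNA it was 53.7%, 88.1% and 95.5%, and for atrium over ventricle 23.9%, 62.7% and 92.4%. False calls were 3.92%, 4.24% and 2.46%. The simulated changes went up and down alike, with no shared shift in replicate 1. In the data far more of the 2601 regions were called, 1944, 2112 and 804. The rates therefore do not carry over to the real calls, least of all those against DNA.

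The numbers of the replicates are shared between groups. Deviations from the group means of same-numbered atrial and ventricular libraries correlated at 0.234 to 0.829, which meets the criterion of 0.1 for treating the numbers as pairs. This comes from replicate 1: within replicates 2 to 5 the same correlations were -0.0166 to 0.0428. Numbers of RNA and DNA libraries did not pair (-0.0362 to 0.0581). A fit with the replicate number as a block was run for each comparison.

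Alternatives were RLE factors in edgeR, the Wald test of DESeq2 1.42.0, library totals, scaling on the Neg regions, limma voom with a variance per group, a fit without robust estimation, other filters, all 15 libraries in one fit, the replicate block, a test against a 1.5-fold change and leaving out each library. Alternatives added after the data were seen were a term for replicate 1, replicates 2 to 5 alone, replicate 1 alone, a filter on RNA counts, a mean DNA count of at least 300 and leaving out each gene of a list that passed. Tables were joined with Python 3.11.15 and pandas 2.3.3.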

Results

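Enhancer activity was measured in the hearts of wild-type mice with a massively parallel reporter assay carried by adeno-associated virus (AAV9). In this assay a pool of candidate sequences is delivered as AAV genomes, and the RNA made from each sequence is set against the amount of its DNA in the virus. The pool was given to newborn pups on postnatal day 0, and atria and ventricles were collected on postnatal day 7. The series title names enhancers selective for a heart chamber as its subject. The 15 libraries formed 3 groups of 5: atrial RNA, ventricular RNA and AAV DNA. Counts covered 3820 regions of 400 bp of the mouse genome (mm10), of which 1909 had their midpoint inside a protein-coding gene. Total counts ran from 877773 to 1271527 in the replicate 1 RNA libraries, from 1718563 to 2369985 in the other atrial libraries, from 2862596 to 3781726 in the other ventricular libraries and from 2312820 to 2958271 in the DNA libraries. A region with 0 counts could therefore hold up to 3.42 CPM (counts scaled by the library total) in the shallowest library and up to 0.793 CPM in the deepest, at 3 counts and for counting error only. Nothing in the labels says that the replicates of a group came from separate animals. P-values of tests between libraries therefore measure the spread between these samples, which may be technical. Permutation p-values over regions or pairs of regions measure the spread between regions, taken as independent, and not that between libraries.

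The replicate 1 RNA libraries stood apart from replicates 2 to 5 in both chambers. Atrial replicate 1 had 765 regions with 0 counts and ventricular replicate 1 had 700, near the 657 to 731 of the DNA libraries, while replicates 2 to 5 had 71 to 85 in atrium and 36 to 66 in ventricle. A set of 488 regions had 0 counts in all 5 DNA libraries, which allows a share of up to 1.30 CPM in the shallowest of them. These regions held 0.0197% and 0.0162% of the counts in atrial and ventricular replicate 1, against 3.34% to 3.86% in atrial and 3.93% to 4.20% in ventricular replicates 2 to 5. Across all regions, log2(CPM + 1) of atrial replicate 1 correlated with ventricular replicate 1 at r = 0.968 and with atrial replicates 2 to 5 at a mean r of 0.645. In the 1177 regions with a mean DNA count of at least 300, atrial replicate 1 correlated with atrial replicates 2 to 5 at 0.925, and ventricular replicate 1 with ventricular replicates 2 to 5 at 0.954. At mean DNA counts of 100 to under 300 the values were 0.736 in atrium and 0.811 in ventricle. At 10 to under 100 they were 0.555 and 0.623. These correlations are across regions, which are not independent replicates. The comparisons below used the 2601 regions with a mean DNA count of at least 10. The DNA libraries may not be the input of replicates 2 to 5, as described in the closing sections. This uncertainty bears on every RNA over DNA value and call below.

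**Figure D1:**
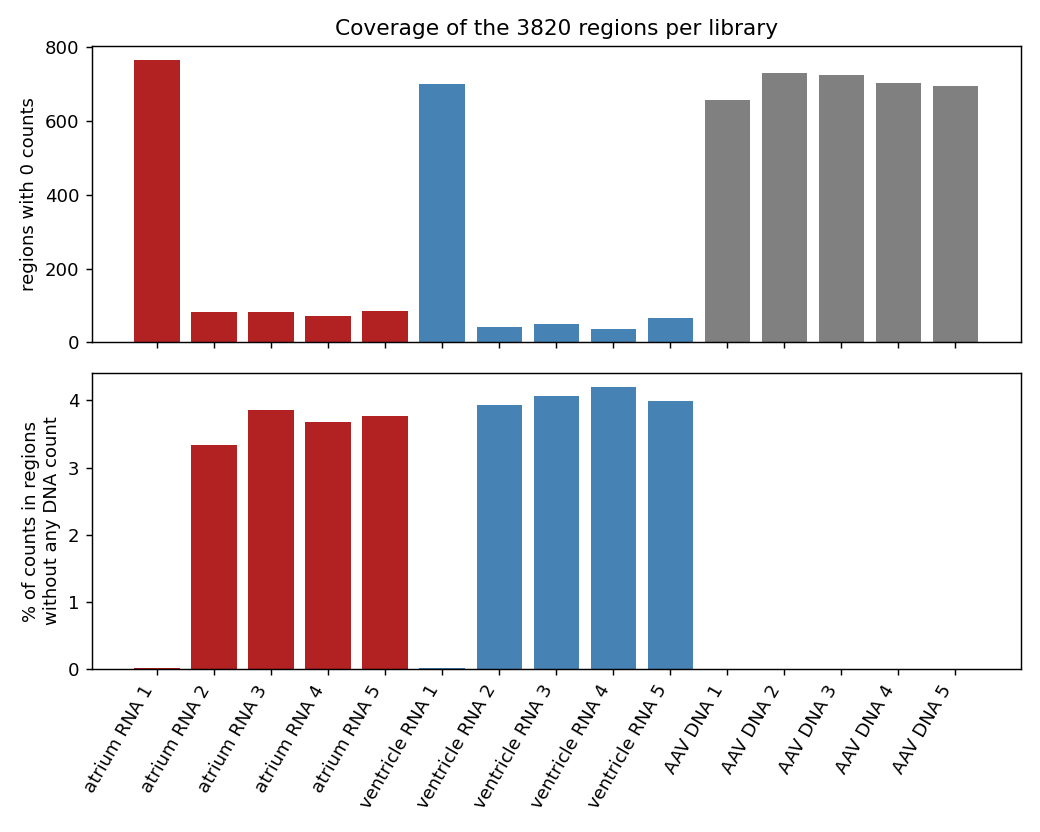
Regions with 0 counts (upper bars) and percent of counts in the 488 regions without a DNA count (lower bars), for each of the 15 libraries. Replicate 1 of both chambers (765 and 700) is near the DNA libraries (657 to 731) in the number of empty regions, and replicates 2 to 5 carry 3.34% to 4.20% of their counts in regions without DNA.

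Among regions whose atrial RNA and DNA libraries did not overlap, the highest RNA over DNA belonged to a region on chromosome 4 with no protein-coding gene within 100 kb (chr4:105364498-105364897), at 1889 ± 178 CPM in RNA and 14.8 ± 3.52 CPM in DNA (SD, n = 5), a log2 ratio of 6.99 ± 0.16 (SE). Next came a region inside Slc8a1, the cardiac sodium-calcium exchanger (chr17:81481598-81481997), at 486 ± 98.8 CPM in RNA against 8.73 ± 2.36 in DNA and a log2 ratio of 5.78 ± 0.21. A region near Hint1 reached 5.68 ± 0.56, and one inside Kcnd2, a subunit of the transient outward potassium channel (chr6:21267836-21268235), 5.26 ± 0.19. Regions near S1pr1, a sphingosine-1-phosphate receptor (chr3:115622269-115622668), and near Adamts15, a secreted protease (chr9:30848229-30848628), had log2 ratios of 5.04 ± 0.24 and 4.99 ± 0.31. The other 4 of the 10 highest of these had no gene within 100 kb and lay on chromosomes 3, 3, 1 and 13 with log2 ratios of 5.44, 5.19, 5.15 and 5.10. The 10 adjusted p-values were at most 1.8e-06. These 10 regions had mean DNA counts of only 11.2 to 52.8. At mean DNA counts of 10 to under 100 the median log2 ratio of all regions was already 1.24 in atrial replicates 2 to 5. The ranking was not adjusted for this.

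Of the 2601 regions, 999 had more atrial RNA than DNA, 945 had less and 657 did not pass the test. At a difference of at least 2-fold, 730 were higher and 543 lower. The 4 lowest regions were nearly silent in atrium. The folds given for them are over pooled counts scaled by library totals, without TMM factors. A region inside Ahdc1 (chr4:133016211-133016610) had 1 RNA count in the 5 atrial libraries against 155 DNA counts, a ratio 109-fold lower in RNA with a 95% counting interval of 19.5 to 4289. A region inside Xkr6 (chr14:63681477-63681876) had 3 RNA and 208 DNA counts, 48.6-fold lower (16.6 to 235.6), and one near Glis2 (chr16:4586564-4586963) had 1 and 52, 36.4-fold lower (6.54 to 1439). A region inside Gm3095 (chr14:3948897-3949296) had 6 and 270 counts, but this gene is 1 of a family of near-identical copies and its counts are uncertain. In Ahdc1, Xkr6 and Glis2, the fitted log2 ratio rested on single counts: it moved from -6.44 to -7.83 without atrial replicate 3, from -5.70 to -6.60 without replicate 4 and from -4.86 to -6.33 without replicate 5, respectively. The median log2 RNA over DNA was lower in regions with more DNA. In replicates 2 to 5 it was 1.24 at mean DNA counts of 10 to under 100, 0.28 at 100 to under 300 and -0.59 at 300 or more, and in replicate 1 it was 0.92, 0.28 and -0.54. With library totals in place of TMM factors the split was 1312 higher and 600 lower, with scaling on the Neg regions 1264 and 644, because these scalings moved the median of all regions by 0.48 and 0.40 on the log2 scale.

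In ventricle, the same chromosome 4 region stood at 1964 ± 71.1 CPM in RNA against 14.4 ± 3.47 in DNA (SD, n = 5), a log2 ratio of 7.10 ± 0.14 (SE). The region near S1pr1 reached 6.42 ± 0.15, the region near Adamts15 6.11 ± 0.22, a region inside Insr, the insulin receptor (chr8:3187531-3187930), 5.59 ± 0.13, a region near Vcam1, an endothelial adhesion molecule (chr3:116072598-116072997), 5.43 ± 0.14, and a region inside Slc20a2, a phosphate transporter (chr8:22521114-22521513), 5.36 ± 0.18. Regions without a gene within 100 kb on chromosomes 1 and 18 had log2 ratios of 5.79 ± 0.16 and 5.77 ± 0.10. The largest fitted value, 9.85 ± 1.58, belonged to a region inside Rbm20, a splicing regulator of titin (chr19:53801883-53802282), at 11758 ± 6567 CPM against 12.7 ± 0.719 in DNA. That value came from replicates 2 to 5 only: the log2 ratio was 10.1 there and 0.13 in replicate 1, and in atrium 9.65 and -0.79. A region inside 2200002J24Rik (chr7:30706503-30706902) likewise had 5.96 in replicates 2 to 5 and 2.69 in replicate 1, and the atrial value near Hint1 (chr11:54879983-54880382) was 5.93 and 2.95. The ventricular regions of this ranking had mean DNA counts of 11.2 to 109. At 10 to under 100 the median log2 ratio of all regions was 1.38 in ventricular replicates 2 to 5, for which the ranking was not adjusted.

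In ventricle 1129 regions had more RNA than DNA, 983 had less and 489 did not pass. The 4 lowest regions were the Gm3095 region with 6 RNA and 270 DNA counts, a region inside Hip1, an endocytic adaptor (chr5:135488873-135489272), 23.2-fold lower over pooled counts, a region on chromosome 17 without a gene within 100 kb (chr17:4626158-4626557), 21.4-fold lower, and a region near Btg2, an antiproliferative factor (chr1:134093098-134093497), 17.6-fold lower. These folds are scaled by library totals, without TMM factors, and the fitted log2 ratio near Btg2 was -4.34. The chromosome 17 region was abundant in the virus, at 28572 ± 3226 CPM in DNA and 1272.5 ± 506 CPM in ventricular RNA (SD, n = 5). Leaving out ventricular replicate 2 moved the fitted log2 ratio of the Gm3095 region from -5.70 to -6.83. The split was 1371 higher and 732 lower with library totals, and 1215 and 852 with scaling on the Neg regions, which moved the median of all regions by 0.37 and 0.16.

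The RNA over DNA values of the chambers correlated across regions at r = 0.941. Unchanged groups simulated against the same DNA libraries gave r = 0.198, and the covariance was 2.70 against a simulated 0.0135. With DNA replicates 1 and 2 for the atrium and 3 to 5 for the ventricle, r was 0.935. The simulation held only the spread of counts and libraries, with no mismatch between the DNA libraries and the delivered pool. Such a mismatch would raise r in the same way, and dividing the DNA libraries cannot remove it. The correlation alone therefore does not show shared activity. In both chambers 908 regions were higher than DNA, against 434 for independent lists, and 822 were lower, against 357, while 35 were called in opposite directions. The lists are not independent, since both use the same DNA libraries, and such a mismatch would raise this overlap too. The overlap therefore does not show shared activity either.

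Between the chambers, the largest atrial excess among regions whose libraries did not overlap was at a region 7404 bp from Myl7, the atrial regulatory myosin light chain (chr11:5889034-5889433). It had 1473 ± 322 CPM in atrium and 281 ± 77.5 in ventricle (SD, n = 5), 5.25-fold higher, with a log2 fold change of 2.39 ± 0.20 (SE) and an adjusted p of 1.6e-06. A region 8906 bp from Bmp10, a growth factor of the atrial myocardium (chr6:87443218-87443617), was 4.80-fold higher in atrium, and a region 2074 bp from Tbx5, a T-box factor of atrial and conduction cells (chr5:119794240-119794639), 3.70-fold. On the ventricular side, a region inside Tuba8, an alpha-tubulin (chr6:121219496-121219895), was 4.0-fold higher in ventricle, a region 4776 bp from Myh7b, a myosin heavy chain (chr2:155606268-155606667), 3.01-fold, and a region 9978 bp from Myh7, the slow beta-myosin heavy chain (chr14:55004404-55004803), 2.84-fold.

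**Figure D2:**
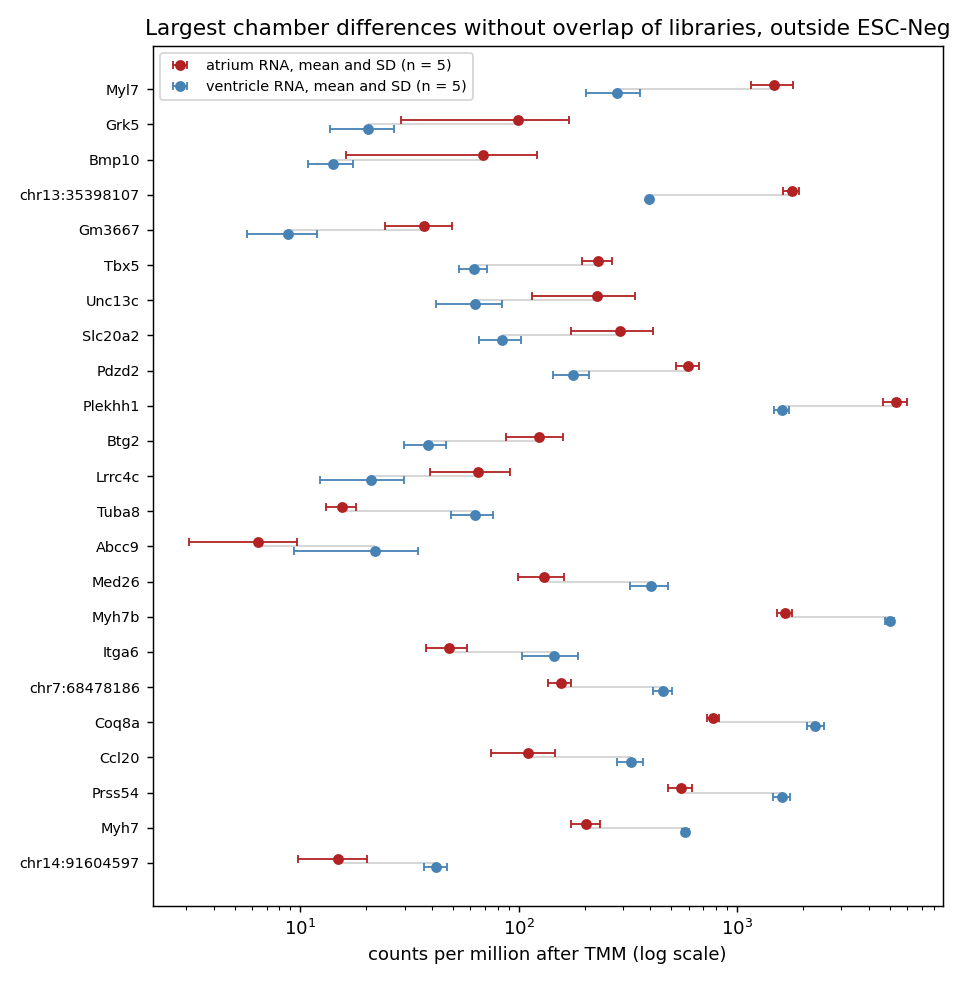
Mean CPM after TMM scaling, on a log axis, with SD over 5 libraries, for 12 regions with the largest differences toward atrium and 11 of those toward ventricle among regions outside ESC-Neg whose atrial and ventricular libraries do not overlap, named by assigned gene or by position. Myl7 lies at 1473 in atrium and 281 in ventricle.

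Of the 2601 regions, 412 were higher in atrium, 392 were higher in ventricle and 1797 did not pass. At least 2-fold were 127 and 79 of them. The 5 atrial and 5 ventricular values did not overlap in 593 regions (22.8%, where chance gives 0.794%), and 569 of these also passed the test. Other regions with large atrial excess lay inside Grk5, a G-protein-coupled receptor kinase (chr19:60939780-60940179, 2.27 ± 0.47 on the log2 scale), on chromosome 13 without a gene within 100 kb (chr13:35398107-35398506, 2.16 ± 0.08), inside Unc13c, a synaptic vesicle protein (chr9:73753550-73753949, 1.85 ± 0.33), inside Slc20a2 (chr8:22505985-22506384, 1.79 ± 0.26), near Pdzd2 (chr15:12749981-12750380, 1.75 ± 0.15), inside Plekhh1 (chr12:79044669-79045068, 1.73 ± 0.09), near Btg2 (1.69 ± 0.26) and near Lrrc4c (chr2:96255055-96255454, 1.63 ± 0.35). A region inside Gm3667, a member of the Gm3095 family, had 2.08 ± 0.41, with the same uncertainty of counting. The Btg2 region was below DNA in both chambers, at -2.77 in atrium and -4.34 in ventricle, so its atrial excess was between 2 low values. The Plekhh1 region was not called against DNA in atrium (-0.17) and was below DNA in ventricle (-1.79).

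Regions with large ventricular excess lay inside Abcc9, a subunit of the cardiac ATP-sensitive potassium channel (chr6:142668171-142668570, -1.79 ± 0.52), inside Med26, a Mediator subunit (chr8:72499591-72499990, -1.63 ± 0.19), near Itga6, an integrin (chr2:71744976-71745375, -1.59 ± 0.24), near Coq8a, a factor of coenzyme Q synthesis (chr1:180210183-180210582, -1.56 ± 0.08), near Ccl20, a chemokine (chr1:83119962-83120361, -1.54 ± 0.22), and near Prss54 (chr8:95596886-95597285, -1.54 ± 0.10). On chromosomes 7 and 14, regions without a gene within 100 kb (chr7:68478186-68478585 and chr14:91604597-91604996) had -1.56 ± 0.13 and -1.50 ± 0.33. The Abcc9 region, at 6.37 ± 3.29 CPM in atrium and 22 ± 12.7 in ventricle, lost its call without ventricular replicate 1 or 2, with voom, against a 1.5-fold change and in replicates 2 to 5 alone (adjusted p = 0.0554).

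At Grk5 and Bmp10 the log2 difference was 3.85 and 3.20 in replicate 1 and 1.82 and 1.79 in replicates 2 to 5. Within replicates 2 to 5 alone, 719 regions differed between chambers, and 663 of the 804 calls were shared with the same sign. The difference between the replicate 1 libraries had the same sign in 684 of those 719 regions (95.1%), with r = 0.870 across regions. A term for replicate 1 against the others gave 881 calls, which included all 804. With scaling on the Neg regions the split was 578 higher in atrium and 226 higher in ventricle, a shift of the median of all regions by 0.16 on the log2 scale. No region named here changed direction under any scaling.

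Identifiers of the regions carry class tags. Of the 419 regions tagged aMTF, 96 were higher in atrium and 45 in ventricle. Of the 524 regions tagged vMTF, 63 were higher in atrium and 148 in ventricle. The aMTF lean was not seen at mean DNA counts of 10 to under 100, with 11 higher in atrium and 16 in ventricle (mean log2 0.05), and the counts were 19 and 4 at 100 to under 300 (0.22) and 66 and 25 at 300 or more (0.28). For vMTF they were 11 and 45 (-0.22), 15 and 45 (-0.19) and 37 and 58 (-0.02). ESC-Neg regions leaned to ventricle in each range, with 3 and 17 (-0.20), 3 and 17 (-0.09) and 16 and 36 (-0.05). At 10 to under 100 the aMTF mean therefore still lay above the vMTF and ESC-Neg means. The mean log2 atrium over ventricle was 0.33 higher in aMTF than in vMTF regions (permutation test over regions, two-sided, p = 1e-05, the smallest these permutations can give). Among aMTF regions that also carry +p300, 68 of 266 were higher in atrium and 29 in ventricle, and among vMTF regions with +p300 it was 44 and 114 of 389. In aMTF regions with -p300 the counts were 28 and 16 of 153, and in vMTF regions with -p300 they were 19 and 34 of 135. Relative to all other regions, the log2 shift was 0.19 for aMTF (camera, adjusted p = 0.00533) and -0.22 for vMTF (adjusted p = 0.00174), and with an estimated correlation the adjusted p-values were 0.0107 and 0.00916. Regions tagged p300AVB leaned to atrium, with 93 higher and 31 lower of 421 (shift 0.20, adjusted p = 0.00533; adjusted p = 0.00297 with an estimated correlation). In GeneAVB regions 183 of 865 were higher in atrium and 117 in ventricle (shift 0.12, adjusted p = 0.109; adjusted p = 0.00916 with an estimated correlation). The 540 regions tagged ESC-Neg, most of which the group column calls Neg, had 22 higher in atrium and 70 higher in ventricle (shift -0.20, adjusted p = 0.0136; adjusted p = 0.0320 with an estimated correlation). With scaling on the Neg regions these counts were 42 and 35, and the class lost its call with DESeq2, without a filter, with filterByExpr and with the RNA filter.

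Against DNA, 288 of the vMTF regions were higher and 127 lower in atrium, and 339 and 126 in ventricle. Of the aMTF regions 200 were higher and 123 lower in atrium, and 199 and 142 in ventricle. ESC-Neg regions had 142 higher and 222 lower in atrium, and 195 and 210 in ventricle. Measured per library against the ESC-Neg regions, the mean log2 RNA over DNA of aMTF regions was 0.77 ± 0.09 in atrium and 0.44 ± 0.10 in ventricle (SD, n = 5), a difference of 0.33 (exact permutation test, two-sided, p = 0.00794, the smallest possible with 5 against 5; adjusted p = 0.0212 over 8 classes). It was 0.33 in replicate 1 and 0.33 in replicates 2 to 5, where the exact p of 0.0286 is the smallest that 4 against 4 can give. This difference had the same sign in 5 of the 5 same-numbered pairs, which the exact test treats as unpaired. For vMTF regions the values were 0.97 ± 0.08 in atrium and 0.97 ± 0.11 in ventricle, a difference of 0.00 (exact permutation p = 0.968). So the vMTF lean to ventricle was not seen against ESC-Neg regions, which leaned the same way. Over regions, the mean log2 value of aMTF exceeded that of ESC-Neg by 0.72 in atrium (permutation p = 1e-05) and 0.40 in ventricle (p = 0.00023), and that of vMTF by 0.93 and 0.94 (p = 1e-05 in both). Against all other regions, the vMTF shift was 0.74 in atrium (camera, adjusted p = 2.7e-06; adjusted p = 0.00198 with an estimated correlation) and 0.96 in ventricle (adjusted p = 4.1e-08; 0.00763 with an estimated correlation). The aMTF shift was 0.46 in atrium (adjusted p = 0.00639; 0.0619 with an estimated correlation) and 0.27 in ventricle (adjusted p = 0.138). GeneAVB regions lay at -0.30 in atrium (adjusted p = 0.0484; 0.0895 with an estimated correlation) and -0.42 in ventricle (adjusted p = 0.0486; 0.185 with an estimated correlation). p300AVB regions lay at -0.36 in ventricle (adjusted p = 0.0486; 0.0149 with an estimated correlation), calls that several other settings ended. Without the filter on DNA counts, aMTF minus ESC-Neg over regions turned to -0.58 in atrium and -0.95 in ventricle. The values of vMTF minus ESC-Neg turned to -0.42 and -0.45.

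**Figure D3:**
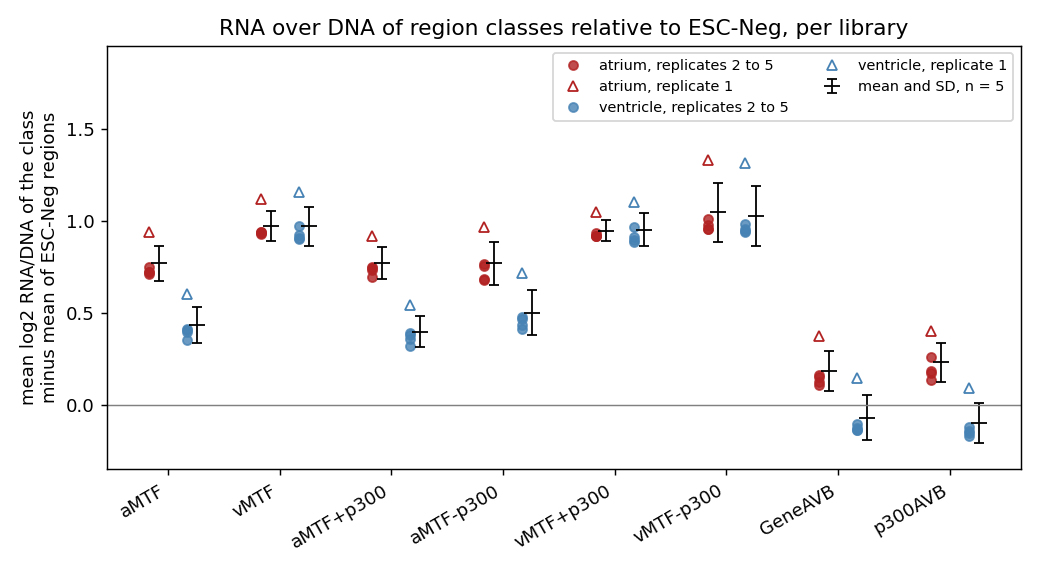
Mean log2 RNA over DNA of each region class minus that of the ESC-Neg regions, 1 point per library (triangles replicate 1, circles replicates 2 to 5), with mean and SD over 5 libraries per chamber. The aMTF classes lie higher in atrium (0.77) than in ventricle (0.44), and the vMTF classes are level (0.97 and 0.97).

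Regions were grouped by their assigned gene into lists of cardiac genes. Of 38 regions at genes of atrial identity, 11 were higher in atrium and 2 in ventricle (13 and 3 when adjusted over the list alone). The 11 included regions at Myl7, Bmp10 and Tbx5 (above), Kcnj5, a subunit of the atrial acetylcholine-gated potassium channel (chr9:32292601-32293000, 1.25 ± 0.11 on the log2 scale), and Nppb, a natriuretic peptide (chr4:147969386-147969785, 0.89 ± 0.08). The Kcnj5 and Nppb regions were below DNA in both chambers, at -0.72 and -0.91 in atrium and -1.86 and -1.69 in ventricle. Their atrial excess was therefore between low values. The 2 regions higher in ventricle lay near Smyd2, a lysine methyltransferase (chr1:189933504-189933903, -1.16 ± 0.10), and Nr2f2, an orphan nuclear receptor of atrial identity (chr7:70409905-70410304, -0.77 ± 0.08). The list's mean shift was 0.41 (camera, adjusted p = 0.0149), but adjusted p = 0.330 with an estimated correlation, and without the Myl7 regions the shift was 0.35 (adjusted p = 0.0836). Of 46 regions at genes of ventricular identity, 6 were higher in atrium and 9 in ventricle (the same when adjusted over the list alone), with a shift of -0.11 (camera, adjusted p = 0.365). At Irx4, a homeobox factor of ventricular muscle, regions 7924 and 20772 bp from the gene (chr13:73277346-73277745 and chr13:73290195-73290594) had -1.33 ± 0.12 and -1.01 ± 0.10, and the Kcnd2 region of this list went the other way (1.45 ± 0.16).

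Of 21 regions at sarcomere genes, 5 were higher in atrium and 6 in ventricle (7 and 6 over the list alone). The 5 lay at Myl7 (2 regions), Myl4 (2 regions) and Csrp3, the Myl4 regions named after their values were seen. Besides Myl7 and Myh7, a region inside Csrp3, the muscle LIM protein (chr7:48842270-48842669), had 0.59 ± 0.10 and one inside Ldb3, a Z-disc protein (chr14:34573943-34574342), -0.54 ± 0.08. Of 29 regions at genes of ion channels and calcium handling, 8 were higher in atrium and 6 in ventricle (the same over the list alone). These included Slc8a1 (1.27 ± 0.13) and Camk2d, a calcium-dependent kinase (chr3:126746335-126746734, -0.85 ± 0.09). Cardiac transcription factors had 5 of 43 regions higher in atrium and 9 in ventricle (5 and 10 over the list alone). Outside ESC-Neg, the Irx4, Tbx5 and Nr2f2 regions had the smallest p-values. Besides Tbx5 the 5 lay at Prdm16 (2 regions), Tead1 (0.63) and Myocd (1.0), named after their values were seen. Of 20 regions at genes of mitochondria, fatty acid oxidation and their regulators, 2 were higher in atrium and 3 in ventricle (the same over the list alone). The 3 lay at Esrrb and Esrrg, estrogen-related receptors (chr12:86498831-86499230, -1.07 ± 0.10, and chr1:187836809-187837208, -0.69 ± 0.14), and at Idh2, a mitochondrial dehydrogenase (chr7:80130434-80130833, -0.79 ± 0.13). The 2 lay inside Ppargc1b, a coactivator of these receptors (chr18:61321978-61322377, 0.91 ± 0.12), and inside Mb, myoglobin (chr15:77027674-77028073, 1.23 ± 0.28, with overlapping libraries), the last chosen after its value was seen. None of these 4 lists shifted against the other regions (camera, adjusted p from 0.365 to 0.522, and 0.330 to 0.508 with an estimated correlation). Against DNA no list did so in either chamber (camera, adjusted p from 0.690 to 0.977 in atrium and 0.849 in ventricle). Fry tests a list against no change instead. Its adjusted p between chambers was 0.00583 for sarcomere, 0.00103 for ion channels, 0.00327 for transcription factors and 0.141 for mitochondria. By fry it was 0.000432 for atrial and 0.00103 for ventricular identity. Against DNA, fry gave adjusted p from 2.5e-06 to 0.733 in atrium and from 1.7e-05 to 0.189 in ventricle. In the mitochondrial list the mean shift (0.02) and the direction of the camera test differed in sign.

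Markers of other cell types were rare among the tested regions. Endothelial genes had 2 regions (Apln and Flt1), fibroblast and epicardial genes 1 (Wt1), skeletal muscle genes 1 (Tnnt3), and none of them differed between chambers by the test. Against DNA, the Wt1 region was lower and the Tnnt3 region higher in both chambers, and 1 of the 2 endothelial regions was higher in ventricle. Of 3 regions at smooth muscle genes, the one near Cnn1, calponin (chr9:22095914-22096313), was higher in atrium at 12.8 ± 11.6 CPM against 1.23 ± 1.41 (SD, n = 5), with overlapping libraries and an adjusted p of 0.0153. Its log2 fold change was 3.10 ± 0.90 and moved to 3.99 without ventricular replicate 4. It was 4.90 in replicate 1 and 2.44 in replicates 2 to 5, where the call was lost (adjusted p = 0.0673), as it was with voom, without a filter, with the RNA filter and against a 1.5-fold change. Blood and immune genes and neuron and liver genes had no tested region.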

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

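The tests of the 488 regions without DNA, and those of the ESC-Neg regions by group column and by scaling, were chosen after those results were seen, while the thinning, the DNA-abundance tests and the regrouping of libraries were set before theirs. A test of reads leaking between libraries was also run on the first pattern, was then replaced by the carry-over test and is not used here.

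RNA counts appeared in regions where no DNA library had a count: 831242 counts over the 10 RNA libraries, of which 379 were in replicate 1. Shallow DNA sequencing is opposed as an explanation, since replicate 1 RNA held 0.453% of the 83577 counts that the shares of replicates 2 to 5 would give. That percentage restates the contrast between replicates that prompted the test, so it is not independent evidence. Carry-over of AAV DNA into the replicate 1 RNA libraries is also opposed: in regions with a mean DNA count of at least 300, log2 RNA over DNA of replicate 1 followed that of replicates 2 to 5 with a slope of 0.91 in atrium and 0.946 in ventricle. A candidate explanation is that replicates 2 to 5 received another pool than replicate 1 and the DNA libraries. Of the 639 regions at 0 in both replicate 1 RNA libraries, 88.1% had a mean DNA count under 1, as this would predict. That overlap restates the likeness of replicate 1 RNA to DNA that prompted the test, so it is not independent evidence either. No label gives a batch, and no biological explanation was tested. Under this candidate explanation the DNA libraries may not be the input of replicates 2 to 5.

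RNA over DNA fell with DNA abundance, with a mean slope of -0.389 ± 0.0455 (SD, 10 RNA libraries) on the log2 scale. Sampling error in DNA is opposed by a slope of -0.390 when abundance and ratio came from different DNA libraries. A rarer pool share of more active classes is opposed by the ESC-Neg regions alone, whose slope was at most -0.218 in each of the 10 RNA libraries. Another pool in replicates 2 to 5 as the whole cause is opposed by replicate 1, whose higher slope was -0.296. Compression in amplification and any biological explanation were not tested and stay open.

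ESC-Neg regions were called higher in ventricle more often than in atrium, 70 against 22 (76.1%). After thinning all RNA libraries to 877773 counts the share was 71.1% (95% exact interval 60.1 to 80.5), which argues against the deeper ventricular libraries. Among ESC-Neg regions that the group column calls Neg it was 79.2%, which argues against those assigned to other groups as the source. Under scaling on the Neg regions it was 45.5%, but that scaling sets the centre of these regions, so a global offset between chambers cannot be told apart from a ventricular lean. A difference between the chambers stays open as a biological explanation and was not tested.

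The libraries were regrouped in 100 of the 126 possible splits, and the 3 counts of calls were set against those splits. In each comparison 1 split, the real one, reached the real count, which was 1944 for atrium over DNA, 2112 for ventricle over DNA and 804 between chambers. The highest other splits gave 52, 60 and 0, and among the 13 drawn splits between chambers that part all 5 pairs, the highest other was also 0. Mixed splits hold the group difference inside both arms, which lowers their counts, so they do not give a rate of false calls. If the replicates of a group are technical, the splits cannot exclude a chance difference between the samples.

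A single library lay far from the others of its group in 19 of 31 library and class measures, and all 19 were replicate 1. Chance gives about 1 in 20 for a single measure. The measures are not independent, since classes share regions and the ESC-Neg reference, so that rate is no yardstick for the count. Regions at 0 numbered 765 in atrial and 700 in ventricular replicate 1, and the share of counts in regions without DNA was 0.0197% and 0.0162%. The correlation of log2(CPM + 1) with the mean of the DNA libraries was 0.894 and 0.878, against at most 0.652 and 0.605 in the others. The most abundant region took 5.22% of ventricular replicate 1, against 2.92% to 3.47%. Relative to ESC-Neg, replicate 1 was the highest library in atrium for aMTF (0.94), vMTF (1.12), aMTF with +p300 (0.92), vMTF with +p300 (1.05), vMTF with -p300 (1.33) and GeneAVB (0.37), and in ventricle for aMTF (0.60), vMTF (1.16), aMTF with -p300 (0.72), vMTF with -p300 (1.31), GeneAVB (0.15) and p300AVB (0.092).

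Among named regions, 17 values of single libraries stood apart, 11 of them in replicate 1 RNA libraries. In log2(CPM + 1), ventricular replicate 1 had 4.06 at Rbm20 (others 13.82 to 13.85), 5.83 at 2200002J24Rik, 11.25 at the chromosome 17 region, 10.83 at Plekhh1, 9.08 at the chromosome 7 region, 9.24 at Myh7, 9.89 at Irx4 and 10.59 at Nr2f2. Atrial replicate 1 had 5.64 at Hint1 (others 8.36 to 8.64), 7.44 at S1pr1 and 11 at the chromosome 13 region. Atrial replicate 2 had 6.63 at Lrrc4c, atrial replicate 3 had 7.80 at Myh7 and 0.51 at Ahdc1, atrial replicate 5 had 0.65 at Glis2, DNA replicate 4 had 4.68 at Vcam1 and DNA replicate 3 had 8.87 at Hip1.

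The distance of a class from ESC-Neg differed between chambers by exact permutation tests, adjusted over 8 classes, with atrium above ventricle by 0.33 for aMTF, 0.37 for aMTF with +p300, 0.27 for aMTF with -p300, 0.25 for GeneAVB and 0.33 for p300AVB (adjusted p from 0.0212 to 0.0381). The ESC-Neg regions themselves leaned to ventricle, and against all other regions aMTF with -p300 did not pass between chambers (shift 0.10, camera adjusted p = 0.196; 0.223 with an estimated correlation).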

How the results depend on the processing

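The alternatives added after seeing the data were the term for replicate 1, replicates 2 to 5, replicate 1 alone, the RNA filter, the DNA minimum of 300 and leaving out single genes of a list. No named region reversed under any alternative, and 1583 of 1597 values of named regions kept their side of the threshold; the others were Abcc9 and Cnn1 (5 alternatives each) and, against a 1.5-fold change, Csrp3, Ldb3, Idh2 and Esrrg. With the replicate block there were 1886 calls for atrium over DNA, 2078 for ventricle over DNA and 869 between chambers (778 of the 804 shared), and apart from the GeneAVB and p300AVB classes against DNA the block changed no class or list call. Counts of calls moved with the filter, which changes the regions tested: without a filter 2952 in atrium and 3171 in ventricle, at a DNA minimum of 100 1280 in atrium, at 300 883, 965 and 498 between chambers. Against a 1.5-fold change 181 remained between chambers, since that test asks for more. Without a filter, which adds regions with little or no DNA, aMTF minus ESC-Neg was -0.58 in atrium and -0.95 in ventricle, vMTF minus ESC-Neg -0.42 and -0.45, the ESC-Neg class against the rest 0.96 in atrium, and p300AVB -0.63 in ventricle. At a DNA minimum of 100 aMTF minus vMTF in atrium passed at -0.25. Replicate 1 alone gave aMTF minus ESC-Neg of 0.94 in atrium, 0.60 in ventricle and 0.33 between chambers, vMTF minus ESC-Neg of 1.12 and 1.16, and aMTF minus vMTF of -0.18 in atrium. The GeneAVB class in atrium lost its call with RLE factors (-0.30), library totals (-0.30), Neg scaling (-0.30), voom (-0.28), a DNA minimum of 100 (-0.24) or 300 (-0.17), all 15 libraries (-0.30), the replicate block (-0.29) and an estimated correlation (-0.30), and with 8 of 10 single libraries left out (-0.31 to -0.29). In ventricle GeneAVB lost it with RLE (-0.42), totals (-0.42), Neg scaling (-0.42), voom (-0.42), a minimum of 100 (-0.33) or 300 (-0.26), the replicate block (-0.42) and an estimated correlation (-0.42), and with 6 of 10 left out (-0.43 to -0.41). p300AVB in ventricle lost it with RLE (-0.36), totals (-0.36), Neg scaling (-0.36), voom (-0.36), filterByExpr (-0.38), the replicate block (-0.36) and replicates 2 to 5 (-0.37), and with 8 of 10 left out (-0.37 to -0.35). Between chambers, ESC-Neg lost its call with DESeq2 (-0.20), no filter (-0.19), filterByExpr (-0.19) and the RNA filter (-0.18), and GeneAVB gained one with an estimated correlation (0.12). The atrial identity list lost its call at a DNA minimum of 100 (0.24) or 300 (0.19), with an estimated correlation (0.41), with any list gene within 100 kb (0.26) and without Myl7 (0.35). Except where the filter is named, the cause was not tested. Read counts against UMI counts, the series table as a separate source and the motif tests were not run. In simulated counts 23.9% of 1.5-fold changes between chambers were recovered, and thinning all RNA libraries to 877773 counts gave 780 calls against 804.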

Other observations

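The tests on pairs of regions were set before their results were seen, except that the shuffle within classes was added after the result for regions of 1 gene. Regions and genes named here were chosen after their values were seen.

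Several genes had 3 tested regions called in 1 direction and none in the other. Of 5 tested regions at Irx4, 3 were higher in ventricle and none in atrium. Rbpms, an RNA-binding protein of muscle, had 3 of 10 higher in atrium and none in ventricle, Tcf7l1, a Wnt pathway factor, 3 of 5, Nav1 3 of 4, Ampd3, an AMP deaminase, 3 of 4, Lamb3, a laminin chain, 3 of 6 and Sardh, a mitochondrial enzyme, 3 of 6. At Trabd2b the regions were mixed, with 1 higher in atrium and 3 in ventricle of 6. Among regions tagged ESC-Neg some differed strongly between chambers: a region on chromosome 11 (22629578 to 22629977) without a gene within 100 kb was 3.14-fold higher in atrium, and a region near Rara, a retinoic acid receptor (chr11:98926399-98926798), was 2.66-fold higher in ventricle.

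One hypothesis was that regions assigned to 1 gene share their chamber preference. Over 1440 pairs of non-touching regions of 377 genes, log2 atrium over ventricle correlated at r = 0.0848 across pairs (one-sided permutation of regions, p = 0.0005, the smallest 2000 permutations can give), and 80 of 135 pairs with both called had the same direction. Shuffling regions within their class left a permutation p of 0.003, which argues against shared class as the whole cause, so a weak common preference per gene may exist. A second hypothesis was that adjacent 400-bp regions share their preference. Over 98 such pairs r was 0.0948 (one-sided permutation p = 0.177), with a bootstrap 95% interval of -0.0525 to 0.233, which includes the value within genes. The bound written beforehand, a p of 0.05 or more, was met and would have counted against this hypothesis; after the result was seen it was judged too lax, since 98 pairs cannot exclude an r of 0.0848, and the question was left open.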
